A study of Homo sapiens with 12 samples.

How the data were processed

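Gene expression was measured by RNA sequencing in primary AML cells sorted for low ROS from 12 patients, 5 monocytic and 7 primitive by the labels, with 1 library each. The cells were thawed and sorted without culture or treatment. Per the labels, libraries were stranded and poly(A)-selected with dUTP marking of the second strand, and were read from a single end. The deposited table holds raw counts, whole-number reads per gene and library with no normalization, as deposited by the authors. The submitters' processing notes name bcl2fastq 2.19.0, Trimmomatic 0.36, STAR 2.6.0c, Subread 1.6.1 with featureCounts, DESeq2 1.16.1 and R 3.4.1, with the GRCh38 build. The annotation release and the strand setting of the counting step are not given in the sources used here.

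The table had 56870 genes. XIST, TSIX, JPX, FTX and Y-linked genes, 516 in all, were left out, which left 56354. Counted as Y-linked were genes annotated only on the Y chromosome and all rows from the first of them to the mitochondrial genes. Of the gene names, 29 read like dates, as spreadsheet programs write them, and were not mapped back to genes, and 2 names occurred more than once. Coordinates, gene types and exon overlaps came from GENCODE release 29 for the 29688 names that matched, and 17 list symbols were found under an older name through RefSeq synonyms.

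Differences between monocytic and primitive libraries were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as design (14790 genes), counts were scaled by TMM, and quasi-likelihood models with a term for the group were fitted with 10 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. The log2 fold change is monocytic minus primitive, and its standard error is the fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM values use a prior count of 2. The p-values measure the spread between libraries, each from a separate patient. In the fit with a term for the group only, that spread also holds the difference between the library sets described below.

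Of the gene lists, 26 were written before the data were examined, and so were the main test and the rule for named genes. Each list was tested with camera (limma 3.58.1) with an inter-gene correlation estimated from the data, and the p-values were adjusted over the 26 lists. List scores, the mean log2 CPM of the tested members, were compared by exact two-sided permutation over the 792 splits of 12 libraries into 5 and 7, and over the 300 splits that keep the number of each group within each library set. The lists cover monocyte and macrophage markers, stem and progenitor markers, LSC17 genes, the anti-apoptotic and the pro-apoptotic BCL2 family, nuclear and mitochondrially encoded oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, fatty acid oxidation, purine biosynthesis, amino acid transporters, the NADPH oxidase and antioxidant enzymes. They also cover MHC class II, interferon response, inflammatory response, HOX genes, cell cycle, neutrophil granule genes, T and NK cells, B and plasma cells, erythroid cells, megakaryocytes, dendritic cells and immediate early genes. A further 4 lists were added after the data were seen.

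The rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean log2 CPM of at least 3 and groups that do not overlap, leaving out clone-based names, immunoglobulin, T cell receptor and HLA genes. It also named 14 genes whatever their result (BCL2, MCL1, BCL2A1, BCL2L1, BAX, CD14, ITGAM, CD68, FCGR1A, LILRB4, CD34, KIT, PTPRC and MPO) and up to 4 members of each list with the smallest p, 130 genes in all. Named beyond the rule, after their values were seen, were CD36, ACADVL, SLC2A1, ATIC, GART, SLC7A1, SLC7A6 and SOD2, each gene named from the added lists, MT-ND6, RP11-1143G9.4 and AC005329.7.

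Total counts per library ranged from 11.8 to 27.1 M (mega). A floor of 3 counts, the upper limit that a count of 0 allows, corresponds to 0.111 to 0.255 CPM and covers counting error only. The widest gap in the totals divided the libraries into a deeper and a shallower set of 6 each. The pipeline was tested on simulated data, in which 200 of 14512 genes, drawn from those above a minimum mean count, were changed. The simulation had no difference between the library sets. Its dispersions came from a fit with the set as a term, so recovery in the real data may differ. The test recovered 13% of the genes changed 2-fold and 64% of those changed 4-fold, with 1 false call and 0 sign errors. Libraries of 1 group were checked for duplicates, and the lowest chi-square per degree of freedom between any pair was 72.4.

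The alternatives were DESeq2 size factors, upper quartile factors, no filter on low counts, at least 1 CPM in 5 libraries, the DESeq2 1.42.0 Wald test, limma voom with sample weights, robust dispersion, the replicate number as a block, the same 10 libraries without the block, and each library left out. For lists they were also a preset correlation of 0.01 and exact permutation. Added after the data were seen were the library set as a term, each set alone, and a fit without genes overlapped on the opposite strand over at least 10% of their exons. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.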

Results

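RNA was sequenced from primary leukemia cells of 12 patients with acute myeloid leukemia (AML). The cells were thawed and sorted, without culture or treatment, for a low level of reactive oxygen species (ROS), a fraction that the labels describe as enriched for leukemia stem cells (LSCs). The labels call 5 of the specimens monocytic and 7 primitive, with 1 library per patient, so every p-value measures the spread between these patients' libraries. Total gene counts were 13.5, 14.002, 27.1, 23.4 and 25.8 M (mega, counted reads) in monocytic libraries 1 to 5. They were 23.2, 24.7, 11.8, 13.8, 12.4, 12.5 and 27.1 M in primitive libraries 1 to 7. The totals fell into a deeper set of 6 libraries (23.2 to 27.1 M; 3 monocytic, 3 primitive) and a shallower set of 6 (11.8 to 14.002 M; 2 monocytic, 4 primitive). The first principal component of log2 CPM (counts scaled to library size) held 43.6% of the variance and separated these sets, and the second held 25.7% and separated monocytic from primitive libraries. Genes annotated as antisense took 0.0934% to 0.178% of counts in the shallower set and 0.0204% to 0.0612% in the deeper set. Values within each set are therefore given beside the main differences.

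**Figure D1:**
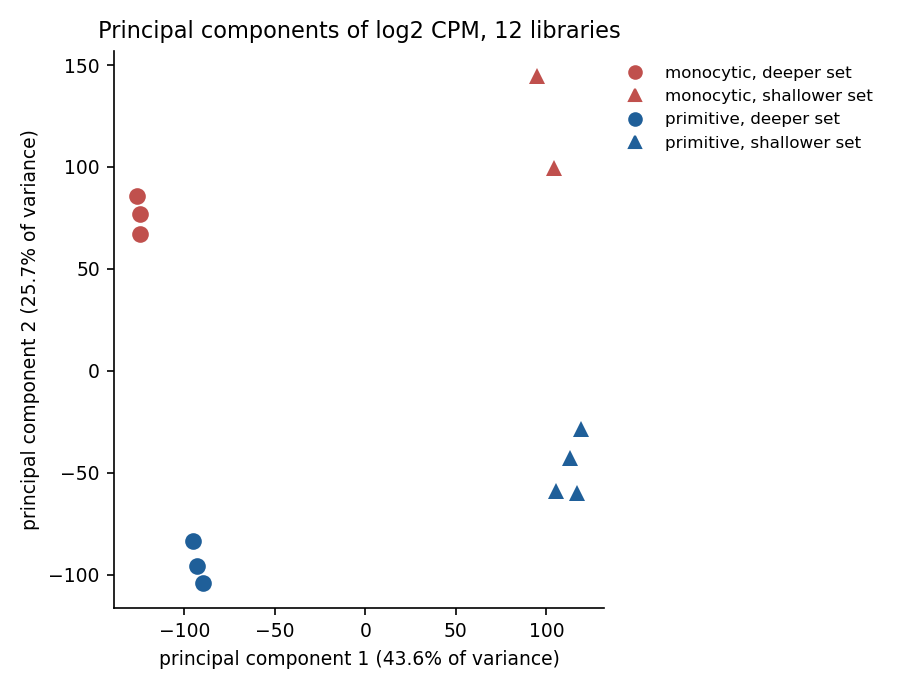
Principal components of the log2 CPM values of 14790 genes in 12 libraries; each axis gives the share of variance in percent, red marks monocytic and blue primitive libraries, circles the deeper and triangles the shallower set. The library sets part along the first component and the groups along the second.

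**Figure D2:**
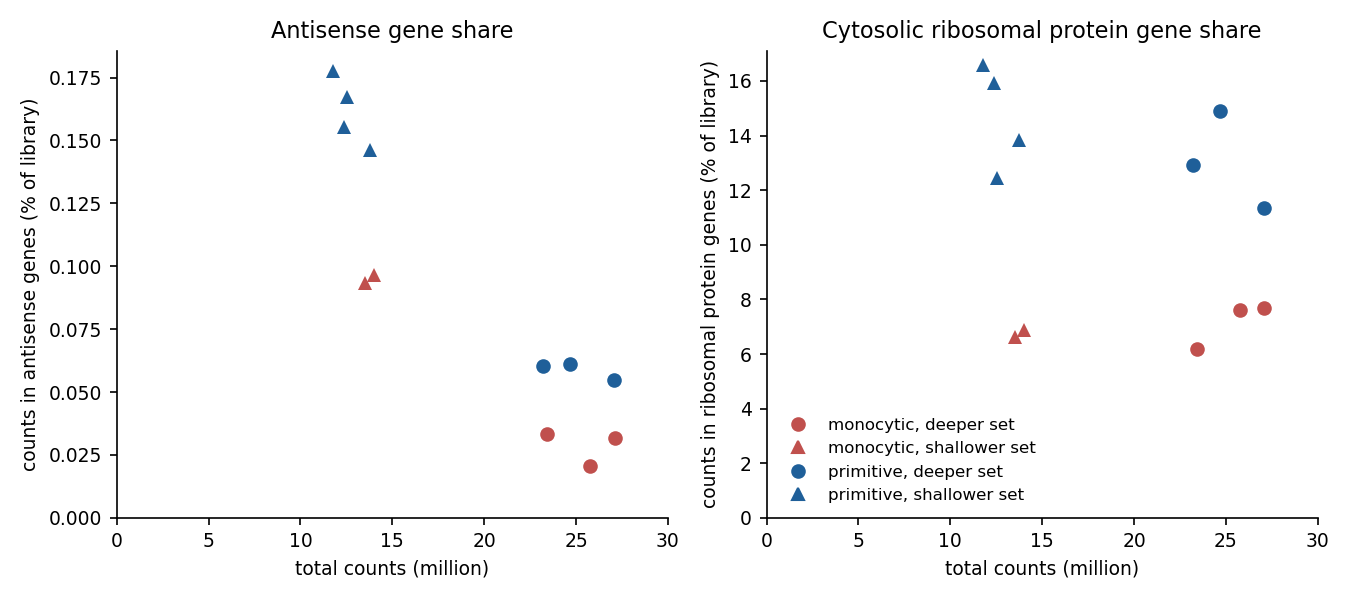
Share of each library's counts, in percent, in antisense genes with matched names (left) and in cytosolic ribosomal protein genes (right) against its total count in M; each point is 1 library. All 6 shallower libraries lie above all 6 deeper ones in antisense share, and all 7 primitive libraries lie above all 5 monocytic ones in ribosomal protein share.

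The comparison asked how ROS-low cells of monocytic AML differ in expression from those of primitive AML. Monocyte and macrophage markers were higher in the monocytic libraries, with 26 of 28 past the threshold and 0 lower. Stem and progenitor markers were lower, with 14 of 22 tested past the threshold and 0 higher. BCL2, the anti-apoptotic gene whose protein the drug venetoclax inhibits, was 3.83-fold lower in monocytic than in primitive libraries, and MCL1 did not pass the test. Its relative BCL2A1 was 6.27-fold higher, with a log2 fold change of 2.65 that was 1.89 (adjusted p = 0.0659) without monocytic replicate 5 and 0.80 (adjusted p = 0.497) by limma voom. Of metabolic genes, 24 of 75 nuclear genes of oxidative phosphorylation were higher and 0 lower, 9 of 21 of glycolysis were higher and 2 lower, and 5 of 17 of purine biosynthesis were lower and 1 higher. None of these 3 lists passed the camera test (adjusted p = 0.226, 0.145 and 0.466 with an estimated correlation).

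Of 14790 genes tested, 1617 were higher and 1182 lower in the monocytic libraries, 2799 in all, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2290 differed at least 2-fold. The groups did not overlap for 1618 genes, against 0.253% of genes by chance. Within the deeper set 1066 genes passed and within the shallower set 1120. Of 2724 genes called in all libraries and tested in both sets, 2721 had the pooled direction in each set. The sets are the libraries that chose these genes, so a high share was likely beforehand and is no independent support. With the library set as a term, chosen after the data were seen, 4307 genes passed (2285 higher, 2022 lower), and 2759 of them were also called without it, all in the same direction. Without monocytic replicate 1 the lower genes numbered 757, and with upper quartile scaling 1280 genes were higher and 1691 lower.

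The 10 genes with the largest rise were APOBEC3A, CD300E, F5, MARCO, HK3, EPB41L3, FCN1, AQP9, LGALS2 and VCAN. They include secreted and membrane proteins of monocytes such as the lectin FCN1 (1446 ± 1820 CPM, SD, n = 5, against 2.48 ± 4.62, n = 7) and the proteoglycan VCAN (2479 ± 1863 against 4.76 ± 8.10 CPM). HK3, a hexokinase of myeloid cells, stood at 243 ± 105 against 0.390 ± 0.576 CPM. MARCO, a scavenger receptor, had 2287 counts over the 5 monocytic libraries and 3 over the 7 primitive ones, so no fold is given for it. The 10 genes with the largest fall were SPON1, CD34, NPR3, AIF1L, ITGA9, MMP28, KIAA0125, VWA1, ROBO4 and TNFRSF4. The natriuretic peptide receptor NPR3 was at 4.50 ± 6.92 against 228 ± 97.4 CPM, and the integrin subunit ITGA9 at 2.68 ± 3.06 against 109 ± 88.7 CPM. SPON1 varied between 0.123 and 178 CPM among primitive libraries and was too low for a test in the deeper set. By limma voom its adjusted p was 0.321, and voom also ended the calls of APOBEC3A, AQP9, EPB41L3, TNFRSF4 and VWA1 (adjusted p from 0.0513 to 0.0612).

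Monocyte and macrophage markers had a mean log2 fold change of 5.70 (monocytic minus primitive, as for all fold changes here). The list as a whole was higher than other genes (camera, adjusted p = 0.0260 with an estimated correlation, but 0.0554 with the library set as a term). Adjusted over the list alone, 27 members were higher. The list score, the mean log2 CPM of its members, was 8.52 ± 0.69 (SD, n = 5) against 2.37 ± 1.05 (n = 7), with an exact two-sided permutation p of 0.00126, the smallest that 792 splits can give. It differed by 6.34 within the deeper set and 6.21 within the shallower set. CD14, the lipopolysaccharide co-receptor (GRCh38, chromosome 5, 140631728 to 140633701), was at 350 ± 199 against 1.35 ± 2.16 CPM. The inhibitory receptor LILRB4 rose by 7.63 ± 1.05 (log2, SE), the beta-glucan receptor CLEC7A by 4.91 ± 0.61 and the integrin ITGAM by 2.57 ± 0.70. Lysozyme (LYZ) was the most abundant of these at 34028 ± 16873 against 159 ± 253 CPM, with 34.0% of its exon length overlapped by a gene on the opposite strand. FCGR1A, which shares sequence with close copies, rose by 2.92 ± 0.93 (adjusted p = 0.0451). Its adjusted p lay between 0.0583 and 0.0949 without any 1 of 9 libraries (monocytic 1 to 5, primitive 1, 4, 6 and 7), 0.0568 under upper quartile scaling and 0.0528 with no filter on low counts. CD68 was at 1.42 ± 0.756 against 0.847 ± 1.14 CPM (adjusted p = 0.684), but another gene on the same strand covers 81.7% of its exon length, so its counts are uncertain. CD36 had a log2 fold change of 2.56 ± 1.07 (adjusted p = 0.118).

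**Figure D3:**
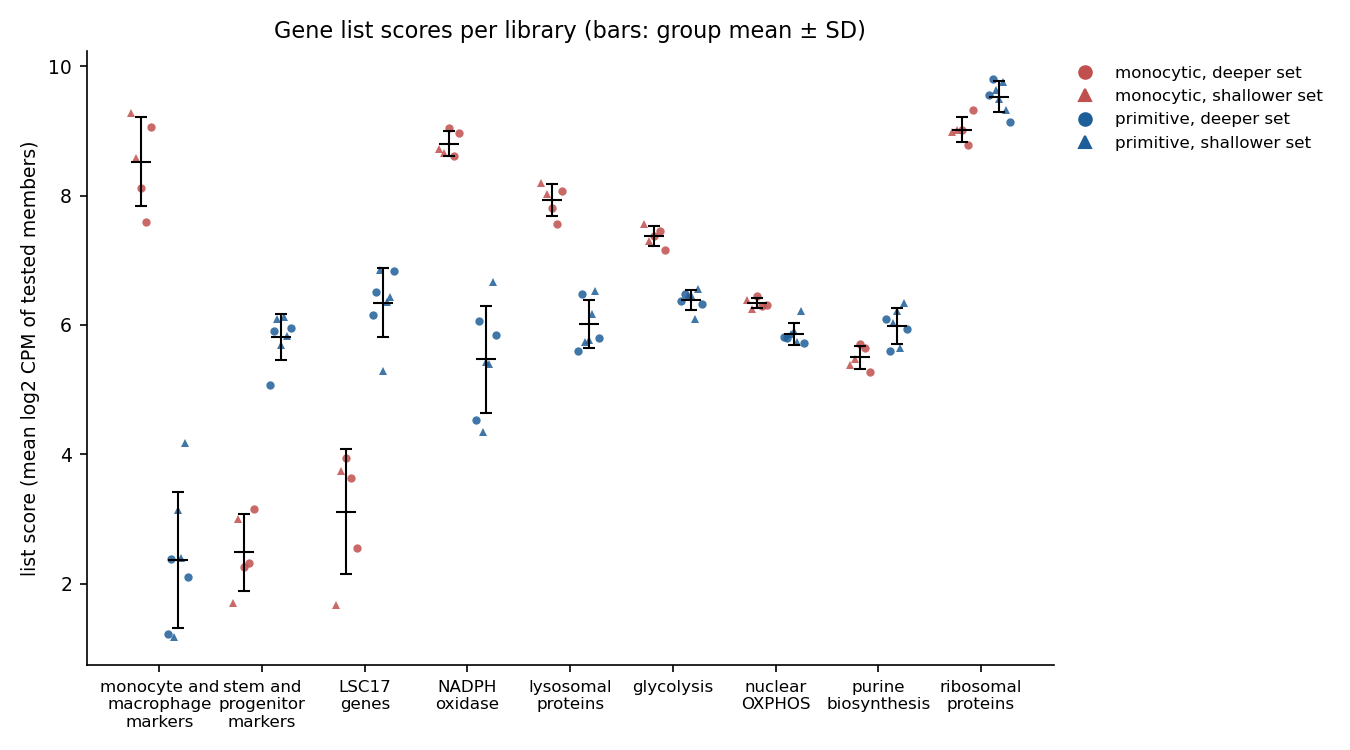
Scores of 9 gene lists in 12 libraries; the y axis is the mean log2 CPM of a list's tested members, each point is 1 library, and bars give the group mean and SD. Scores of the marker lists, the NADPH oxidase, the lysosomal list, glycolysis and nuclear oxidative phosphorylation do not overlap between the groups. For nuclear oxidative phosphorylation the nearest libraries lie at 6.25 (monocytic) and 6.21 (primitive).

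Stem and progenitor markers had a mean log2 fold change of -3.23 (camera, adjusted p = 0.0155 with an estimated correlation), and 16 were lower when adjusted over the list alone. Their score was 2.48 ± 0.59 against 5.81 ± 0.35 (exact permutation p = 0.00126) and differed by -3.07 and -3.59 within the deeper and shallower sets. In the deeper set alone 8 members were lower and 1 higher. CD34, the surface antigen of hematopoietic progenitors (chromosome 1, 207880972 to 207911402), was at 16.5 ± 32.9 against 892 ± 445 CPM. Its log2 fold change was -5.76 ± 1.36 (SE; adjusted p = 0.0120), but -8.96 without monocytic replicate 5, -5.12 in the deeper set (adjusted p = 0.133) and -9.36 in the shallower set (adjusted p = 0.00705). The stem cell factor receptor KIT was at 4.66 ± 5.12 against 69.1 ± 56.3 CPM, and the transcription factor ERG fell by 4.12 ± 0.58 on the log2 scale. EGFL7 and HOPX had log2 fold changes of -4.19 each. With the library set as a term, the camera test gave both marker lists an adjusted p of 0.0554. Of the LSC17 genes, a published stemness score that shares CD34 with the previous list, 12 of 17 were lower and 0 higher (13 lower adjusted over the list alone). Their mean log2 fold change was -2.80, with an adjusted p = 0.0744 with an estimated correlation. SMIM24 (-4.29 ± 0.57), ZBTB46 (-2.42 ± 0.37) and the cyclin-dependent kinase CDK6 (-1.54 ± 0.27) were among them, as was KIAA0125 (-5.11 ± 0.88), an older name of FAM30A.

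BCL2 (chromosome 18, 63123346 to 63320128) was at 11.5 ± 4.77 CPM (SD, n = 5) in monocytic and 44.1 ± 9.96 CPM (n = 7) in primitive libraries, a log2 fold change of -1.94 ± 0.33 (SE; adjusted p = 0.00228). All 5 monocytic libraries lay below the lowest primitive one. Within the deeper set the log2 fold change was -1.73 (adjusted p = 0.0205) and within the shallower set -2.43 (adjusted p = 0.0596). BCL2A1, an NF-kB target with a related protective role, had a log2 fold change of 2.65 ± 0.70 (adjusted p = 0.0202), which was 1.89 without monocytic replicate 5 (adjusted p = 0.0659) and 0.80 by limma voom with sample weights (adjusted p = 0.497). Within the deeper set its log2 fold change was 2.68 (adjusted p = 0.248) and within the shallower set 2.63 (adjusted p = 0.0230). MCL1 was abundant in both groups, at 1829 ± 960 and 1626 ± 1096 CPM, with a log2 fold change of 0.17 ± 0.53 (adjusted p = 0.879) and a 95% interval from -1.02 to 1.36. Its sign turned without monocytic replicate 2 (-0.10), without primitive replicate 7 (-0.02) and under upper quartile scaling (-0.05) or voom (-0.14), and it was -0.27 within the deeper and 0.59 within the shallower set. BCL2L1, which encodes BCL-XL, stood at -0.64 ± 0.35 (adjusted p = 0.229) and BCL2L2 at -0.62 ± 0.29 (adjusted p = 0.158). So 1 of the 5 tested anti-apoptotic genes was higher and 1 lower, also when adjusted over the list alone, and 0 were higher without monocytic replicate 5, while voom called 0 higher and 2 lower (list adjusted p = 0.537 with an estimated correlation). Of 9 tested pro-apoptotic members, 3 were higher and 0 lower, the same numbers as adjusted over the list alone, with a list adjusted p = 0.226 with an estimated correlation. These were the BH3-only genes BID (1.38 ± 0.27), BBC3 (2.67 ± 0.59), which encodes PUMA, and BCL2L11 (1.73 ± 0.48), which encodes BIM. BCL2L11 lost its call without monocytic replicate 2, monocytic replicate 5 or primitive replicate 5 (adjusted p from 0.0503 to 0.0643) and by voom (adjusted p = 0.117), where 2 pro-apoptotic genes were higher, and BBC3 was at 1.77 without monocytic replicate 5. BAX was at 0.41 ± 0.41 (adjusted p = 0.553) and PMAIP1 at -0.81 ± 0.49 (adjusted p = 0.287).

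**Figure D4:**
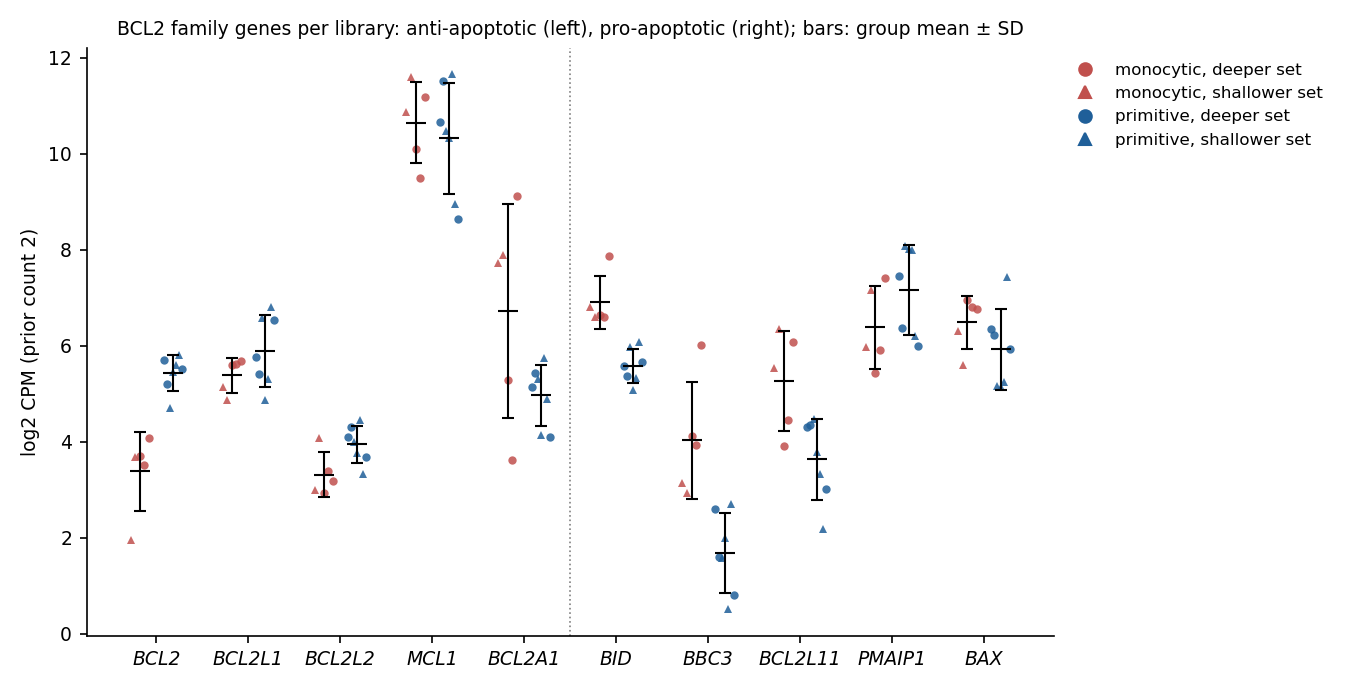
Expression of 10 BCL2 family genes, as log2 CPM with a prior count of 2, in 12 libraries; bars give the group mean and SD. BCL2 lies lower in all 5 monocytic libraries than in any primitive one, while MCL1 overlaps between the groups.

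Nuclear genes of oxidative phosphorylation were higher for 24 of 75 tested members and lower for 0 (28 higher adjusted over the list alone). The mean log2 fold change was 0.47, with an adjusted p = 0.226 with an estimated correlation and 1.59e-08 with a preset one. The list score was 6.34 ± 0.08 against 5.86 ± 0.17 (exact permutation p = 0.00126) and differed by 0.57 and 0.39 within the deeper and shallower sets. Examples are SDHB of complex II (1.08 ± 0.15), NDUFA6 of complex I (1.09 ± 0.17) and the cytochrome oxidase subunits COX7B (0.98 ± 0.16) and COX8A (1.57 ± 0.25). A gene on the same strand overlaps 34.5% of COX8A. The count of higher members was 15 under upper quartile scaling, 14 with no filter on low counts and 36 with the library set as a term. Without genes overlapped on the opposite strand, 14 of the 50 members left were higher. Here and below, that fit also leaves out genes whose names did not match the annotation, so its counts do not show the effect of overlap alone. Of the 13 mitochondrially encoded subunits, 0 passed in either direction by edgeR, DESeq2 or limma voom, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.926 with an estimated correlation). Their mean log2 fold change was -0.08, against a score difference of 0.07. In the tricarboxylic acid cycle, OGDH (1.164 ± 0.29) and IDH3G (1.003 ± 0.25) were higher among 21 genes and 0 were lower, as they were adjusted over the list alone (list adjusted p = 0.642 with an estimated correlation). That count was 4 without monocytic replicate 2 or primitive replicate 6, and 1 of 16 without genes overlapped on the opposite strand.

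In glycolysis, 9 of 21 genes were higher and 2 lower (10 and 3 adjusted over the list alone), with a list adjusted p = 0.145 with an estimated correlation. The score differed by 0.98 (exact permutation p = 0.00126), by 0.94 and 1.05 within the sets. PGAM1 rose by 1.95 ± 0.26 and pyruvate kinase PKM by 1.62 ± 0.27. The lower genes were lactate dehydrogenase B (LDHB, -1.41 ± 0.28), overlapped on the same strand over 33.4% of its exons, and the glucose transporter SLC2A1 (-1.47 ± 0.44). They numbered 1 without any 1 of 6 libraries (monocytic 1, 2, 4 and 5, primitive 1 and 2), with no filter on low counts and by voom. In fatty acid oxidation, 4 of 21 genes were higher and 1 lower, also adjusted over the list alone (list adjusted p = 0.591 with an estimated correlation). The acyl-CoA synthetase ACSL1 rose by 3.30 ± 0.62, DECR1 by 0.85 ± 0.22, ACADVL by 0.79 ± 0.24 and ACSL3 by 0.90 ± 0.23, and HADH was at -0.92 ± 0.23. Without monocytic replicate 1 there were 2 higher genes, and ACSL3 lost its call (0.68, adjusted p = 0.0514). Upper quartile scaling also gave 2, and DECR1 lost its call there (0.65, adjusted p = 0.0642).

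Of 17 purine biosynthesis genes, 5 were lower and 1 higher (7 and 2 adjusted over the list alone). The list score was 5.50 ± 0.18 against 5.98 ± 0.27 (exact permutation p = 0.0101) and differed by -0.34 and -0.63 within the sets, but the camera test gave an adjusted p = 0.466 with an estimated correlation. The 2 isoforms of IMP dehydrogenase, which commits IMP to guanine nucleotides, went opposite ways, IMPDH2 at -2.01 ± 0.27 (110 ± 32.0 against 443 ± 107 CPM) and IMPDH1 at 1.22 ± 0.21. PPAT, the first enzyme of the pathway, was at -1.78 ± 0.24, PAICS at -1.44 ± 0.28, ATIC at -0.92 ± 0.22 and GART at -0.92 ± 0.25. Without monocytic replicate 5, 2 genes were higher, as by DESeq2 and voom. Of 13 amino acid transporters, 6 were higher and 3 lower, also adjusted over the list alone (list adjusted p = 0.466 with an estimated correlation). SLC7A7 rose by 7.13 ± 1.38, SLC43A2 by 3.17 ± 0.43 and SLC36A4 by 2.17 ± 0.41. The glutamine carrier SLC38A1 was at 18.6 ± 11.4 against 334 ± 240 CPM (-4.17 ± 0.69), and SLC7A1 (-1.32 ± 0.29) and SLC7A6 (-0.93 ± 0.28) were also lower.

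**Figure D5:**
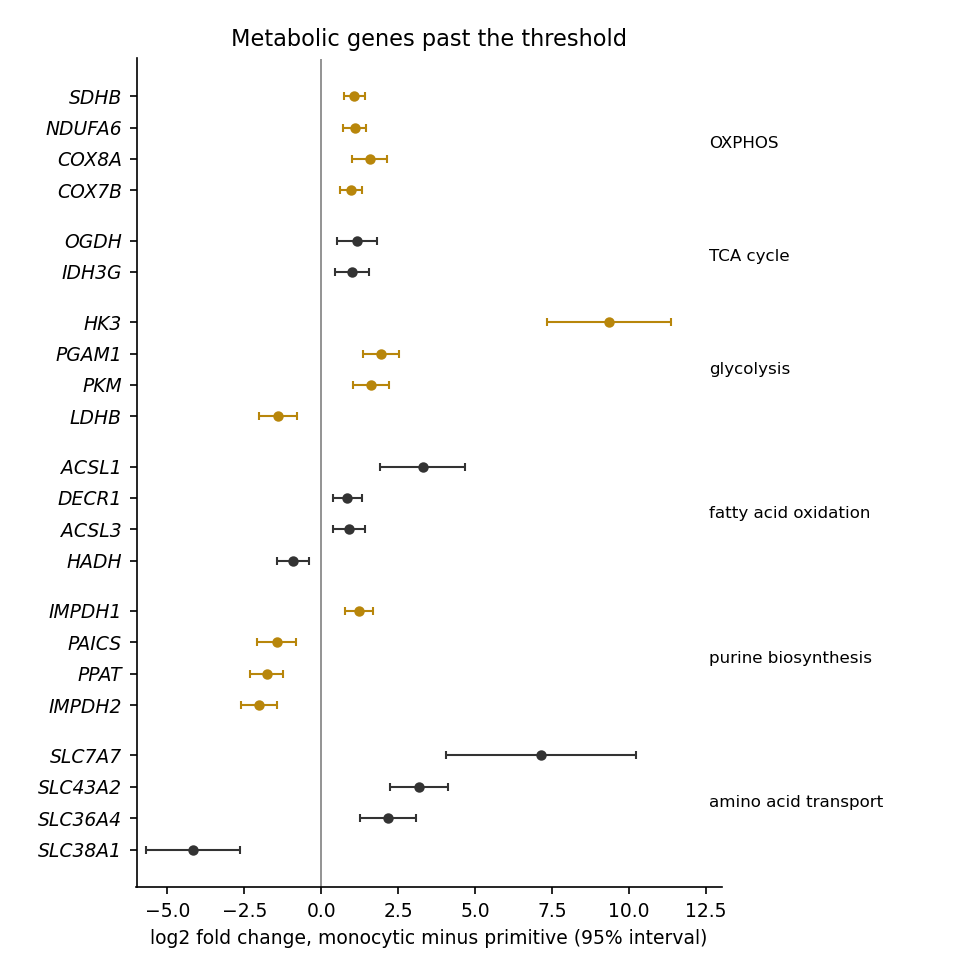
Log2 fold changes (x axis, monocytic minus primitive) of 22 metabolic genes named by the fixed rule and past the threshold; points are edgeR estimates and bars 95% intervals from their standard errors. In purine biosynthesis IMPDH1 lies above 0 and PAICS, PPAT and IMPDH2 below it.

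Because the cells were sorted for low ROS, genes that make or remove ROS were compared. Of the 6 genes of the phagocyte NADPH oxidase, which produces superoxide, 4 were higher and 0 lower, also adjusted over the list alone (list adjusted p = 0.172 with an estimated correlation). The score was 8.80 ± 0.19 against 5.47 ± 0.82 (exact permutation p = 0.00126), with differences of 3.397 and 3.22 within the sets. The catalytic subunit CYBB was at 1260 ± 628 against 16.1 ± 15.0 CPM, and NCF1, which has near-identical pseudogenes, rose by 5.88 ± 0.54. CYBA rose by 1.20 ± 0.34, a call lost without any 1 of 6 libraries (monocytic 3 to 5, primitive 1, 4 and 5; adjusted p from 0.0516 to 0.0615) and with no filter (adjusted p = 0.0525). Among 21 antioxidant enzymes, 5 were higher and 0 lower (6 and 1 adjusted over the list alone; list adjusted p = 0.466 with an estimated correlation). Heme oxygenase HMOX1 was at 371 ± 528 against 1.47 ± 0.663 CPM, glutathione reductase GSR rose by 1.40 ± 0.26, SOD2 by 1.31 ± 0.40, GPX4 by 0.94 ± 0.23 and PRDX5 by 0.78 ± 0.23. PRDX5 lost its call without any 1 of 7 libraries (monocytic 3 and 4, primitive 1, 3, 4, 5 and 7; adjusted p from 0.0538 to 0.0907). It also lost it under upper quartile scaling (adjusted p = 0.0881), with no filter (0.0697) and without genes overlapped on the opposite strand (0.0554). The higher enzymes numbered 3 without primitive replicate 1, 5 or 7 and with no filter on low counts. Upper quartile scaling gave 3 higher and 2 lower and DESeq2 7 higher and 2 lower. Without primitive replicate 2, with a minimum of 1 CPM in 5 libraries, by voom, with the library set as a term and without genes overlapped on the opposite strand, 1 was lower.

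Of 18 inflammatory and NF-kB response genes, 10 were higher and 0 lower (12 and 1 adjusted over the list alone; list adjusted p = 0.407 with an estimated correlation). The score differed by 2.12 (exact permutation p = 0.00505), by 1.90 and 2.51 within the sets. The interleukin-1 receptor antagonist IL1RN was at 100.0 ± 30.1 against 0.573 ± 0.404 CPM, and NFKBIZ (4.24 ± 0.63), TNF (4.69 ± 1.02) and NFKBIA (1.75 ± 0.32) also rose. TNF was at 2.63 without monocytic replicate 5. The higher members numbered 5 without monocytic replicate 5 or primitive replicate 7 and 6 without primitive replicate 5, and 1 was lower under upper quartile scaling, by DESeq2, by voom and with the library set as a term. Of 20 interferon response genes, 8 were higher and 0 lower (13 higher adjusted over the list alone; list adjusted p = 0.537 with an estimated correlation). This count fell to 1 without monocytic replicate 5 and was 4 or 5 without any 1 of primitive replicates 2 to 7, and 2 passed with the library set as a term, 4 by DESeq2 and 1 by limma voom. OAS1 rose by 3.06 ± 0.49 and CXCL10 by 4.79 ± 1.20. IFI6 had a log2 fold change of 3.01 ± 0.79, which was 0.999 without monocytic replicate 5 (adjusted p = 0.0851), and MX1 one of 4.01 ± 1.07, which was 0.80 (adjusted p = 0.288). DESeq2 gave neither gene an adjusted p. Both lost their calls by voom (adjusted p = 0.0732 and 0.182) and with the library set as a term (0.0611 and 0.0659), and CXCL10 by voom (0.0707). Among 10 genes of MHC class II presentation, CTSH (5.57 ± 1.01) and IFI30 (4.89 ± 1.22) were higher and 0 were lower, also adjusted over the list alone (list adjusted p = 0.722 with an estimated correlation). IFI30 lost its call without monocytic replicate 5 (2.96, adjusted p = 0.0667), when 1 member of the list was lower, and 40.2% of its exon length lies under another gene of the same strand. The list had 1 higher member with a minimum of 1 CPM in 5 libraries and 1 lower by voom. HLA-DRA was at 1.04 ± 0.41 (adjusted p = 0.0939).

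Of 20 immediate early and heat shock genes, IER3 (3.41 ± 0.62), ZFP36 (1.67 ± 0.44) and JUNB (1.52 ± 0.48) were higher and 0 were lower, with 2 higher adjusted over the list alone (list adjusted p = 0.642 with an estimated correlation). The count was 1 without monocytic replicate 4 or 5, and 1 of 17 without genes overlapped on the opposite strand. IER3 was at 2.25 without monocytic replicate 5. ZFP36 lost its call without monocytic replicate 4 or 5 (adjusted p from 0.0509 to 0.0587), and JUNB without any 1 of 9 libraries (monocytic 3 to 5, primitive 1, 2, 3, 5, 6 and 7; adjusted p from 0.0554 to 0.147, with 0.99 without monocytic replicate 5), under upper quartile scaling (0.0766), with no filter (0.0622) and with the library set as a term (0.0910). Among 14 HOX genes and cofactors, 0 passed by edgeR or DESeq2 and 3 were lower by limma voom, with 0 at an unadjusted p under 0.05 in edgeR (list adjusted p = 0.844 with an estimated correlation). Among 25 cell cycle genes, 0 passed by edgeR, 1 was higher by DESeq2 and 4 by limma voom, with 2 at an unadjusted p under 0.05 in edgeR (list adjusted p = 0.797 with an estimated correlation). The cell cycle score differed by 1.04 within the deeper and by -0.02 within the shallower set, and 1 gene was higher without primitive replicate 1. The HOX list had a mean log2 fold change of -0.05 and a median of 0.32, and its score differed by -3.27 and 1.90 within the sets. In the deeper set alone 5 HOX list members were lower by edgeR and 0 higher, and in the shallower set alone 0 passed. Both lists had 0 members past the threshold adjusted over the list alone.

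Markers of other blood cells were counted to see what else the sorted fraction held. Of 7 tested neutrophil granule genes, CAMP (4.66 ± 0.96), RNASE3 (4.47 ± 1.03) and CTSG (5.15 ± 1.30) were higher and 0 lower. The higher genes numbered 5 adjusted over the list alone, without monocytic replicate 5 and with no filter on low counts. By camera with an estimated correlation the list adjusted p was 0.466. The list score was 4.79 ± 2.55 against 1.61 ± 1.96 (exact permutation p = 0.0379, and 0.0703 adjusted over the lists). Monocytic replicate 5 was at 1.39 and primitive replicate 4 at 4.27. By voom CTSG lost its call (4.76, adjusted p = 0.0517). MPO, the myeloperoxidase gene, had a log2 fold change of -2.30 ± 1.67 (adjusted p = 0.383), which was 0.47 without primitive replicate 4 and 0.41 by DESeq2. Of 8 dendritic cell markers, IRF4 (3.46 ± 0.91), CD1C (3.90 ± 1.19) and CLEC10A (5.16 ± 1.597) were higher (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.466 with an estimated correlation). CD1C lost its call without monocytic replicate 2 or primitive replicate 3, 5 or 6, and CLEC10A without any 1 of 9 libraries (monocytic 1, 3 and 5, primitive 1, 2, 3, 5, 6 and 7). IRF4 and CD1C lost their calls by voom (adjusted p = 0.0540 and 0.112), and CD1C with no filter (0.0584). CLEC10A was at 8.48 without primitive replicate 4. The count of higher dendritic markers was 1 without any 1 of 8 libraries (monocytic 3 and 5, primitive 1, 2, 3, 5, 6 and 7), and by voom, and 1 was lower without monocytic replicate 5, by DESeq2, by voom and with the library set as a term.

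Of 18 T and NK cell markers, NKG7 (2.602 ± 0.50) was higher and CD6 (-3.85 ± 0.85) lower, also adjusted over the list alone (list adjusted p = 0.797 with an estimated correlation). CD2 stood at -3.11 ± 1.08 (adjusted p = 0.0638), and 2 markers were lower without monocytic replicate 1 or primitive replicate 4 or 7, under upper quartile scaling and without genes overlapped on the opposite strand. The lower markers numbered 3 by DESeq2 and with the library set as a term and 0 by voom, where CD6 was at -3.50 (adjusted p = 0.0631). Of 8 tested B and plasma cell markers, MZB1 (-3.73 ± 0.91) was lower and 0 higher, also adjusted over the list alone (list adjusted p = 0.642 with an estimated correlation), and 2 were lower without monocytic replicate 4, by DESeq2 and with the library set as a term. JCHAIN stood at -4.70 ± 1.75 (adjusted p = 0.0815). Of 11 erythroid markers, TFRC (-1.71 ± 0.43) and HEMGN (-4.58 ± 0.98) were lower and 0 higher, also adjusted over the list alone (list adjusted p = 0.597 with an estimated correlation), and 4 were lower by DESeq2. Of 9 megakaryocyte and platelet markers, 2 were lower, among them VWF (-2.85 ± 0.93), and 0 higher, also adjusted over the list alone (list adjusted p = 0.530 with an estimated correlation). VWF lost its call without any 1 of 9 libraries (monocytic 1, 2, 3 and 5, primitive 2, 3, 5, 6 and 7; adjusted p from 0.0567 to 0.110), which left 1 lower gene. With no filter or robust dispersion VWF also lost its call (adjusted p = 0.0574 and 0.0507) and 1 marker was lower, by voom 0 (VWF 0.0671), and with the library set as a term 1 was higher. The pan-leukocyte gene PTPRC, which encodes CD45, was at 1192 ± 605 against 603 ± 243 CPM (0.98 ± 0.40, adjusted p = 0.111).

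By list, 2 of the 26 passed the camera test with an estimated correlation, 9 with a preset correlation of 0.01 and 13 by exact permutation of the list scores. The preset test added the LSC17, nuclear oxidative phosphorylation, glycolysis, NADPH oxidase, interferon, inflammatory and neutrophil granule lists, whose calls were lost with an estimated correlation.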

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

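The tests in this part were not chosen after the result was seen, but some of the values they covered were. Among these are scores of the gene lists added after the data were seen, and the library shares of antisense and ribosomal protein genes. The highest and the lowest library of each group were compared with the rest of their group for 272 sets of values, and in 20 of them 1 library stood apart by Dixon's criterion (95%). Chance flags about 1 in 20 groups, which makes 13.6 expected, so single cases carry little weight.

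Interferon response genes in the monocytic group had 1 library far above the other 4. Its list score was 7.86, with the next library at 4.35. On the log2 CPM scale MX1 was 9.69 there (next 4.46) and IFI6 9.25 (next 5.75). In the same library IFI30 was at 4.39 (next 1.10), BID at 7.88 (next 6.81) and the pro-apoptotic BCL2 family score at 5.52 (next 5.11). Its scores were the lowest of the group for the tricarboxylic acid cycle, 5.38 (next 6.14), and antioxidant enzymes, 6.28 (next 6.70). Without this library, monocytic replicate 5, 1 interferon response gene remained higher in place of 8. No technical or biological explanation was tested for it.

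Among monocytic libraries, 1 had the lowest BCL2, at a log2 CPM of 1.95 (next 3.52), and the lowest SMIM24, at -0.64 (next 2.29). Another had the lowest OGDH, at 6.92 (next 7.72). Among primitive libraries, 1 had the lowest CD34, at 6.97 (next 9.23), the lowest SMIM24, at 5.999 (next 6.73), and the lowest stem and progenitor score, 5.08 (next 5.69). Another had the highest nuclear oxidative phosphorylation score, 6.21 (next 5.91), the highest SDHB, 6.10 (next 5.81), the highest F5, -1.67 (next -2.76), and the lowest immediate early and heat shock score, 6.004 (next 8.03). The megakaryocyte and platelet score was highest in 1 primitive library, at 4.13 (next 2.29), and CLEC10A in another, at 3.18 (next -0.58).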

How the results depend on the processing

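Tests with the library set as a term, in each set alone and without genes overlapped on the opposite strand were chosen after the data were seen, and all others before. Of 94 named genes past the threshold, 0 turned their direction under any alternative by edgeR, DESeq2 or limma voom. Of them 68 stayed past the threshold in every alternative that gave a value, apart from the 10-library fits and the single sets. DESeq2 size factors kept all 94, and the DESeq2 Wald test kept all 90 to which it gave an adjusted p, but gave none to IFI30, IFI6, MX1 and TNF. Upper quartile factors ended 4 calls, no filter 6, voom 17, robust dispersion 1 and the library set term 3, and leaving out a library ended 3 to 11. The losses were largest in each set alone and with the block. The deeper set alone ended 47 of 92 calls, the shallower set alone 53 of 93 and the 10 libraries with the block 59 of 93. Without the block the 10 libraries ended 14 of 93. Without genes overlapped on the opposite strand, and without names that did not match the annotation, 1 of 84 ended. Upper quartile scaling moved the median log2 fold change of all genes to -0.25, from -0.05 with TMM and -0.06 with DESeq2 factors. Depth limits the low end, since 3 counts correspond to 0.111 to 0.255 CPM. The 13% of simulated 2-fold changes recovered is a separate limit, because those genes were drawn from above a minimum mean count.

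The DESeq2 Wald test called 4017 genes, 1921 of them lower, and shared 2772 with the 2799 of the reported test, but the cause of the higher count was not tested. With the library set as a term 4307 genes passed, 2022 of them lower. In the deeper set alone 1066 passed (632 higher, 434 lower) and in the shallower set alone 1120 (797 higher, 323 lower), with 6 libraries each. Leaving out 1 library gave 2074 to 2681 genes, 1317 to 1560 higher and 757 to 1141 lower, and the fewest without monocytic replicate 1.

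By camera with an estimated correlation 2 lists passed. The number was 9 with a preset correlation, 13 by exact permutation and 4 with no filter. It was 0 with the library set as a term, in the deeper set alone and in the shallower set alone, and 2 to 3 without 1 library. The cause was not tested.

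The replicate number as a block, on 10 libraries, gave 376 genes (281 higher, 95 lower) and 0 lists, against 2119 genes in the same libraries without the block. The numbers do not pair the samples, since the labels give each library a different patient. The libraries of each shared number correlated at -0.67, -0.66, -0.46, -0.41 and -0.37 in their deviations from the group means, and each such pair spans both library sets.

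Changes of direction concerned values that did not pass the test, and the cause was not tested. MCL1 was at -0.054 with upper quartile factors, -0.14 by voom, -0.31 with the block, -0.23 in the 10 libraries without it and -0.27 in the deeper set. MPO was at 0.41 by DESeq2, 0.27 by voom and 1.03 in the deeper set. With no filter the mean of the anti-apoptotic list was 0.28 and that of the B and plasma cell list 0.37. The mitochondrially encoded list was at 0.073 by its scores and 0.13 in the shallower set. Also in the shallower set, BAX was at -0.18, CD68 at -0.58, the HOX list at 0.91, the cell cycle list at -0.51 and the immediate early list at -0.11. Without 1 library, MCL1 ranged from -0.10 to 0.42, MPO from -2.93 to 0.47, the HOX list from -0.31 to 0.26 and the anti-apoptotic list from -0.29 to 0.020. The cell cycle list ranged from -0.026 to 0.82 and the mitochondrially encoded list from -0.33 to 0.27.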

Other observations

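The 4 gene lists here, the tests of the library sets, and the ribosomal comparisons within the sets and with genes of like abundance were chosen after the result was seen. Of 35 genes of lysosomal hydrolases and membrane proteins, 25 were higher in the monocytic libraries and 0 lower (28 higher adjusted over the list alone). The list's mean log2 fold change was 1.89, with an adjusted p = 0.0328 with an estimated correlation over the 4 lists, which was 0.0918 with the library set as a term. Its score was 7.93 ± 0.25 (SD, n = 5) against 6.01 ± 0.37 (n = 7; exact permutation p = 0.00126) and differed by 1.85 and 2.06 within the deeper and shallower sets. The proteases CTSB and CTSD rose by 3.01 and 2.38 on the log2 scale, the saposin precursor PSAP by 3.998, progranulin (GRN) by 4.01, TPP1 by 1.602 and the membrane protein LAMP1 by 0.89.

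Of 85 cytosolic ribosomal protein genes, 21 were lower and 0 higher (24 lower adjusted over the list alone), with a mean log2 fold change of -0.53 and an adjusted p = 0.346 with an estimated correlation. Their share of all counts was 7.01 ± 0.637% (SD, n = 5) against 13.999 ± 1.91% (n = 7; exact permutation p = 0.00126, and 0.00333 within the sets, the smallest possible in each case). RPLP0 was at -1.41, RPL3 at -1.12 and RPS6 at -0.87. The lower genes numbered 12 without monocytic replicate 1 and 13 without monocytic replicate 3, 8 with no filter on low counts, 37 by DESeq2, 41 under upper quartile scaling and 46 by voom, which called 1 higher. Without genes overlapped on the opposite strand, 35 of 76 were lower. Of 19 translation factors, EEF1B2 (-1.44), EEF1A1 (-0.76) and EIF3L (-0.67) were lower and 0 higher (4 lower adjusted over the list alone; list adjusted p = 0.507 with an estimated correlation). That count was 1 without monocytic replicate 1, 3 or 4 or primitive replicate 5 and with no filter, 5 under upper quartile scaling and 7 by voom. By DESeq2 and with the library set as a term, 5 were lower and 1 higher. Of 75 mitochondrial ribosomal proteins, MRPL33, MRPL14, MRPL54 and MRPL34 were higher and MRPL1, MRPS30, MRPS27 and MRPL45 lower (2 higher and 3 lower adjusted over the list alone; list adjusted p = 0.867 with an estimated correlation). The higher ones numbered 2 without any 1 of 6 libraries (monocytic 3 to 5, primitive 3, 5 and 7), and under upper quartile scaling 2 were higher and 11 lower. With no filter 1 was higher, DESeq2 called 9 higher and 10 lower, voom 9 and 7, and the fit with the library set as a term 7 and 8. Without genes overlapped on the opposite strand 2 were higher and 7 lower.

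The lower ribosomal protein expression was weighed against technical explanations. Abundant genes that take counts lower the share of all other genes alike, but relative to the median of 1568 other genes of like abundance, without the 50 most abundant and scaled by library total, the score differed by -0.89 (exact permutation p = 0.00253; -0.83 and -0.98 within the sets), which argues against them as the whole cause. Without that comparison, the list score itself differed by -0.51 over all libraries (exact permutation p = 0.00631). It differed by -0.46 within the deeper and -0.55 within the shallower set (exact permutation p within sets = 0.01), which argues against the library sets. Whether the level falls with monocytic differentiation cannot be told apart from other differences, because the labels divide the groups by it. Across the 7 primitive libraries, the 1 relation computed, Spearman's rho with the monocyte score was -0.21 (exact permutation p = 0.662). Pearson's r was -0.28 (exact permutation p = 0.538), and 0.10 without the 2 farthest libraries. Monocyte scores were 1.17 to 4.17 in these libraries and 7.59 to 9.27 in monocytic ones, so this relation cannot decide the question. Differences between the groups that the labels name stay open and untested.

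The deeper and shallower sets differed in 5172 genes with the group as a term (3067 higher and 2105 lower in the shallower set). Antisense genes whose exons overlap a gene on the opposite strand were higher in the shallower set. Their median log2 difference was 4.01 beyond that of protein-coding genes without overlap, and the counterpart for same-strand overlap was -0.16. The 95% interval, 1.88 to 6.53, came from resampling the 64 antisense genes, so it holds the spread between genes and not between libraries. Genes with counts in the shallower libraries alone could pass the filter, which can raise this difference. Counts of RP11-1143G9.4, opposite LYZ, were 42.6% to 53.6% of those of LYZ in the shallower set and at most 0.00241% in the deeper set, and MT-ND6 had 172 to 250 counts per 1000 of MT-ND5 against 0.626 to 1.37. Reads of both strands entering the counts of the shallower set is a candidate explanation, found in and tested on the same data. Fewer reads would lower MT-ND6 and MT-ND5 alike, so their ratio argues against depth alone, and within each group the lowest shallower antisense share was at least 2.39 times the highest deeper one, which argues against the cell groups as the cause of the set difference.

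Of 100 splits of the 12 libraries into 5 and 7, only the real 1 gave as many as 2799 genes. This does not exclude chance, because only 100 of the 792 splits were run. Splits that mix the groups also carry the group difference within their parts, which lowers their counts. The highest other split gave 2561 and had 5 of 5 libraries of its first part in the deeper set, so it followed the library sets, and the next gave 64. With the library set as a term, the real split gave 4307 genes and the highest of the others 488, again 1 of 100. A test of whether the group difference itself differed between the sets passed for 3 genes, HOXB2 (9.46 on the log2 scale, shallower minus deeper), HOXB3 (10.88) and AC005329.7 (4.87), with 659 at an unadjusted p under 0.05. The number of genes with a count was 19605 ± 779 against 20628 ± 461 (exact permutation p = 0.0202, and 0.01 within sets), and the mitochondrial share was 7.88 ± 3.46% against 9.42 ± 6.13% (exact permutation p = 0.659). The share of antisense genes with matched names was 0.0550 ± 0.0368% in monocytic against 0.118 ± 0.0559% in primitive libraries. Its exact permutation p was 0.0631 over all splits, which does not pass, and 0.00333 within sets, the smallest possible. This share was 0.0204% to 0.0332% against 0.0548% to 0.0612% in the deeper set and 0.0934% to 0.0964% against 0.146% to 0.178% in the shallower set. Antisense genes under unmatched names are not in it, so the direction for all antisense genes is not known.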
